A study of Mus musculus with 20 samples.

How the data were processed

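The samples were 20 RNA sequencing libraries from wild-type mice: FRC at day 5 (n = 4) and day 14 (n = 5), Ly6C-high monocyte-macrophages at day 5 (n = 3) and day 14 (n = 3), and Ly6C-low monocyte-macrophages at day 5 (n = 3) and day 14 (n = 2). The labels describe small numbers of cells per library, sorted a second time into lysis buffer, from pooled inguinal, axillary and brachial nodes. The labels do not say whether replicates came from separate animals or litters, so the p-values measure the spread between libraries, which may be technical in part. The deposited values were raw read counts per gene symbol, made per the submitters' processing notes with STAR 2.7.3a on mm10 and featureCounts. The annotation version, strand setting and treatment of multi-mapping reads were not given in the sources used here. The table held whole numbers in 1 column per sample, and 0 columns of other samples. Positions, lengths and GC content came from the GENCODE M21 annotation, in which 52936 of 55011 symbols (96.2%) were found.

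Each library had 17456 to 24888 genes with a count. Replicates were compared pair by pair with a chi-square per degree of freedom over genes with at least 20 summed counts, and the 26 pairs lay between 5.13 and 91.8, so no pair was a copy or a division of 1 library's reads.

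Differential expression was tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3, by a quasi-likelihood fit with TMM scaling, the filterByExpr low-count filter by group and robust estimation, and a Benjamini-Hochberg adjusted p threshold of 0.05 over all genes tested. The standard error of a log2 change is its size divided by the square root of the F statistic. The FRC comparison used the 9 FRC libraries, the 5 monocyte-macrophage comparisons used the 11 monocyte-macrophage libraries with 4 group means, and the comparison of FRC with monocyte-macrophages used all 20. CPM values are counts scaled to an equal library total. A gene with 0 counts in a group is given as at least a fold against a floor of 3 counts over the group, and a gene with 1 to 3 counts by its ratio with an exact 95% counting interval.

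Gene lists were tested with limma's camera on log CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists with at least 5 measured members. Camera with an estimated correlation and the rotation test fry were run beside it. The 26 lists covered FRC survival and chemokine genes, the lymphotoxin beta receptor and NF-kB organizer program, collagen and matrix, cell cycle, imprinted and fetal growth genes, interferon response, MHC class I and class II, inflammatory cytokines, immediate early and stress genes, cholesterol synthesis, oxidative phosphorylation, classical and nonclassical monocytes, resident macrophages, lysosome and phagocytosis, and markers of dendritic cells, neutrophils, T cells, B cells, NK cells, endothelium, pericytes, adipocyte precursors, erythroid cells, and epithelium or muscle. The number of lists past camera that kept their call with an estimated correlation was 0 of 11 in FRC, 0 of 12 in Ly6C-high cells, 0 of 13 in Ly6C-low cells, 2 of 14 and 4 of 12 between the gates at day 5 and day 14, 0 of 2 for the difference between gates and 0 of 13 for FRC against monocyte-macrophages. With fry, 11, 10, 5, 10, 10, 0 and 11 of these lists kept their call in the same direction, in the same order.

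The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took, for each 2-group comparison, the 8 largest rises and 8 largest falls among genes past the threshold with a mean log CPM of at least 4 and no overlap between the groups' libraries, and 5 each way for the 2 difference comparisons without the overlap condition, passing over predicted genes and pseudogenes. From every list described it added the measured members with the smallest p, up to 4.

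The alternatives were RLE scaling, DESeq2 1.42.0, limma-voom with sample quality weights, no low-count filter, a strict filter (at least 10 counts in every library of a group and a mean of 5 CPM), thinning to the smallest total, each library left out in turn, a 2-fold minimum, replicate number as a block, and other sets of libraries in the fit. The division of the FRC libraries into 2 sets was found in the data, by searching all divisions that cross age for the one that took up most residual variance, and the fits with it were added afterwards. The tests were tried on simulated data with the same group sizes and spread. Of 100 genes each with a planted log2 change of 1 and of 2, they recovered 16% and 77% in FRC, 44% and 75% in Ly6C-high cells, 43% and 74% in Ly6C-low cells, 43% and 78% between gates at day 5, 35% and 69% at day 14, 17% and 50% for the difference between gates, and 14% and 50% for FRC against monocyte-macrophages, with 2 to 9 calls among the genes left unchanged.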

Results

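RNA was sequenced from 20 libraries of cells sorted from pooled skin-draining lymph nodes of wild-type B6 mice at day 5 and day 14 after birth. Fibroblastic reticular cells (FRC), the fibroblasts that build the lymph node scaffold, were sorted as CD45-, CD31-, Pdpn+ and Pdgfra+ and gave 4 libraries at day 5 and 5 at day 14. Monocyte-macrophages were sorted as lineage-negative, CD11b+ and CD64+ cells and divided by surface Ly6C. The Ly6C-high gate gave 3 libraries at each age, and the Ly6C-low gate gave 3 at day 5 and 2 at day 14. Counts were given for 55011 gene symbols. Library totals ranged from 4297084 to 8344895 in FRC at day 5, from 6070972 to 8035347 in FRC at day 14, from 4450281 to 6356107 in Ly6C-high cells at day 5, from 2774126 to 7986686 in Ly6C-high cells at day 14, from 3806024 to 5639316 in Ly6C-low cells at day 5, and from 4698557 to 5410539 in Ly6C-low cells at day 14. A level is given in CPM (counts scaled to an equal library total), mean ± SD over the libraries of a group, and a log2 change as the fitted value ± its standard error, day 14 over day 5 unless another direction is stated. Counting intervals and floors cover counting error only.

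Most of the genes behind the sort followed the gates. Ptprc, which encodes CD45, had 0.981 ± 0.512 CPM in day 5 FRC and 2.97 ± 2.89 CPM in day 14 FRC, against 1913 ± 296, 1822 ± 266, 1151 ± 52.1 and 1637 ± 109.6 CPM in Ly6C-high day 5, Ly6C-high day 14, Ly6C-low day 5 and Ly6C-low day 14 cells. Pdpn had 566 ± 306 CPM in day 5 FRC and 283 ± 147 CPM in day 14 FRC, and Pdgfra had 313 ± 199 and 707 ± 230.4 CPM. They had group means of at most 0.98 and 2.11 CPM in monocyte-macrophages. Fcgr1, which encodes CD64, was between 95.8 and 151 CPM in the monocyte-macrophage groups and at most 0.03 CPM in FRC. Ly6c2 had 289.7 ± 51.4 and 531 ± 90.8 CPM in Ly6C-high cells at day 5 and day 14, and 6 ± 1.52 and 27.1 ± 10 CPM in Ly6C-low cells. Cd3e, Cd19 and Ly6g, markers of lineages that the gate excluded, had group means of at most 3.08, 0.76 and 0.524 CPM in the monocyte-macrophage groups. Klrb1c and Thy1 had at most 1.22 and 2.72 CPM there. Bst2, fixed beforehand with the sort and gate genes, was not low. It had 86.2 and 142 CPM in Ly6C-high and 124 and 139 CPM in Ly6C-low cells at day 5 and day 14. In FRC it had 98.1 and 85.2 CPM.

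The 9 FRC libraries fell into 2 sets that crossed age, although the place of 1 library was uncertain. Day 5 replicates 1, 2 and 3 and day 14 replicate 1 formed library set 1, and day 5 replicate 4 and day 14 replicates 2 to 5 formed library set 2. This division took up 43.5% of the variance left within the ages, the highest share among 210 divisions. The next, with 39.5%, differed only in placing day 5 replicate 2 in the other set. That library had a chi-square per degree of freedom of 42.1 and 40.7 against day 5 replicates 1 and 3, and 47.7 against replicate 4. Its within-age deviations correlated at 0.067 with day 14 replicate 1 and at -0.058 to 0.0075 with day 14 replicates 2 to 5. The fits were not repeated with it in the other set. Lars2, a mitochondrial leucyl-tRNA synthetase gene, was chosen after its values were seen. It lay between 779 and 1240.3 CPM in set 1 and between 386 and 448 CPM in set 2. Pdpn lay between 405 and 877 CPM in set 1 and between 198 and 225 CPM in set 2, and Pdgfra between 191 and 302 CPM in set 1 and between 609.9 and 865 CPM in set 2. Mitochondrial transcripts took 0.811% to 1.31% of counts in set 1 and 0.58% to 0.722% in set 2. Set 1 held 3 of the 4 day 5 libraries and 1 of the 5 day 14 libraries, so FRC counts of called genes, and the named calls lost, are also given with library set as a term in the model. That term was chosen in these same libraries for the residual variance it takes up, so p-values from fits with it may be too small.

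**Figure D1:**
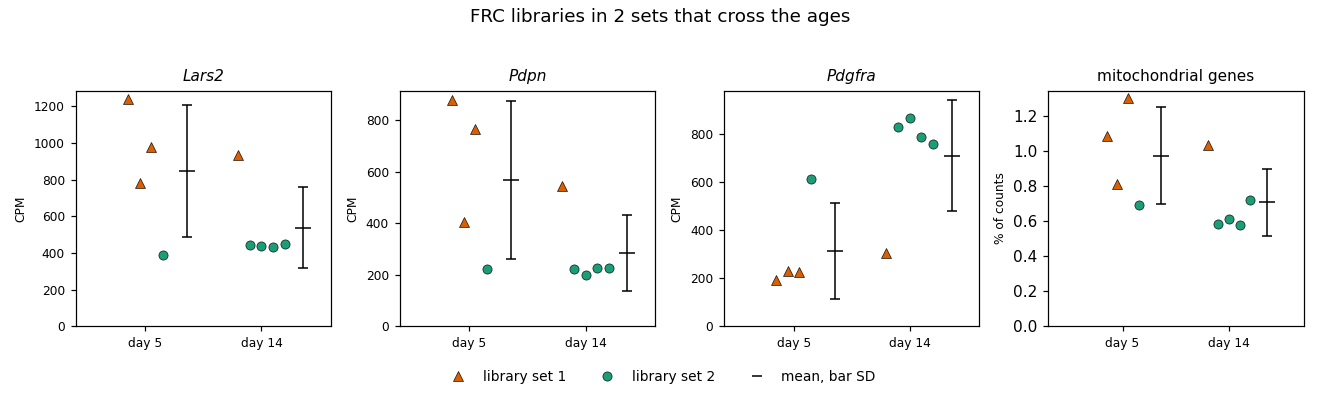
Lars2, Pdpn and Pdgfra in CPM and mitochondrial transcripts in percent of counts, each point 1 FRC library by age, with triangles for library set 1 and circles for library set 2. Set 1 libraries lie at 779 to 1240.3 CPM of Lars2 and set 2 libraries at 386 to 448 CPM, at either age. Lars2 was chosen after its values were seen.

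The comparison of FRC at day 14 with day 5 asked how the stromal cells changed over the days after birth. Cxcl12, the ligand of Cxcr4, rose from 1988 ± 582 to 7997 ± 1257 CPM (log2 change 2.03 ± 0.24). Il7, a survival cytokine of lymphocytes, went from 56.8 ± 13.1 to 184 ± 21 CPM (1.71 ± 0.19), and Tnfsf13b, which encodes the B cell survival factor BAFF, from 10.8 ± 4.85 to 111 ± 12.2 CPM (3.36 ± 0.27). The imprinted gene Dlk1 fell from 181 ± 116 to 14.5 ± 2.23 CPM (-3.62 ± 0.34) and H19 from 426 ± 279 to 23.1 ± 27.5 CPM (-4.17 ± 0.73). Among all genes, the largest rises by the naming rule were in Fam180a (6.10 ± 0.51), the transcription factor gene Zbtb16 (4.26 ± 0.48), the matrix metalloproteinase gene Mmp3 (4.20 ± 0.51) and Gas6, a ligand of the Axl and Mertk receptors, from 42.2 ± 9.46 to 697 ± 245 CPM (4.07 ± 0.32). Stmn2 (3.98 ± 0.56), Igfbp2 (3.96 ± 0.61), Slc45a3 (3.93 ± 0.40) and Inmt (3.78 ± 0.30) rose too. The largest falls were in Klf14 (-4.60 ± 0.37), H19, Nim1k (-4.08 ± 0.59), AW551984 (-3.92 ± 0.48), Capn6 (-3.78 ± 0.40), Dlk1, Cthrc1 (-3.46 ± 0.52) and Sele, which encodes E-selectin (-3.21 ± 0.60). On mm10, Cxcl12 lies on chromosome 6, 117168535 to 117181367, Tnfsf13b on chromosome 8, 10006467 to 10039072, Gas6 on chromosome 8, 13465374 to 13494490 and Dlk1 on chromosome 12, 109452823 to 109463336.

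By edgeR, 2216 of 13916 genes passed, 1117 higher and 1099 lower at day 14, of which 1414 changed at least 2-fold. With library set as a term the count was 1939, 969 higher and 970 lower, and 1449 genes (65.4% of the 2216) were called both ways in the same direction. The count was 4615 without day 5 replicate 4 and 4059 without day 14 replicate 1, which are the set 2 library at day 5 and the set 1 library at day 14. It was 1253 and 1300 without day 5 replicates 1 and 3, and 1125, 1144, 1124 and 1324 without day 14 replicates 2, 3, 4 and 5. Of the 89 named genes past the threshold, 81 still passed with library set as a term, and 68 passed without each library in turn. The 8 lost with the term were Ccl2, Cr2, Cycs, Flt4, Gbp2, Rgs5, Tnnt3 and Vwf. With it the log2 change was 1.89 for Cxcl12, 1.89 for Il7, 3.5955 for Tnfsf13b, 3.68 for Gas6, -3.97 for Dlk1 and -4.17 for H19, each past the threshold.

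**Figure D2:**
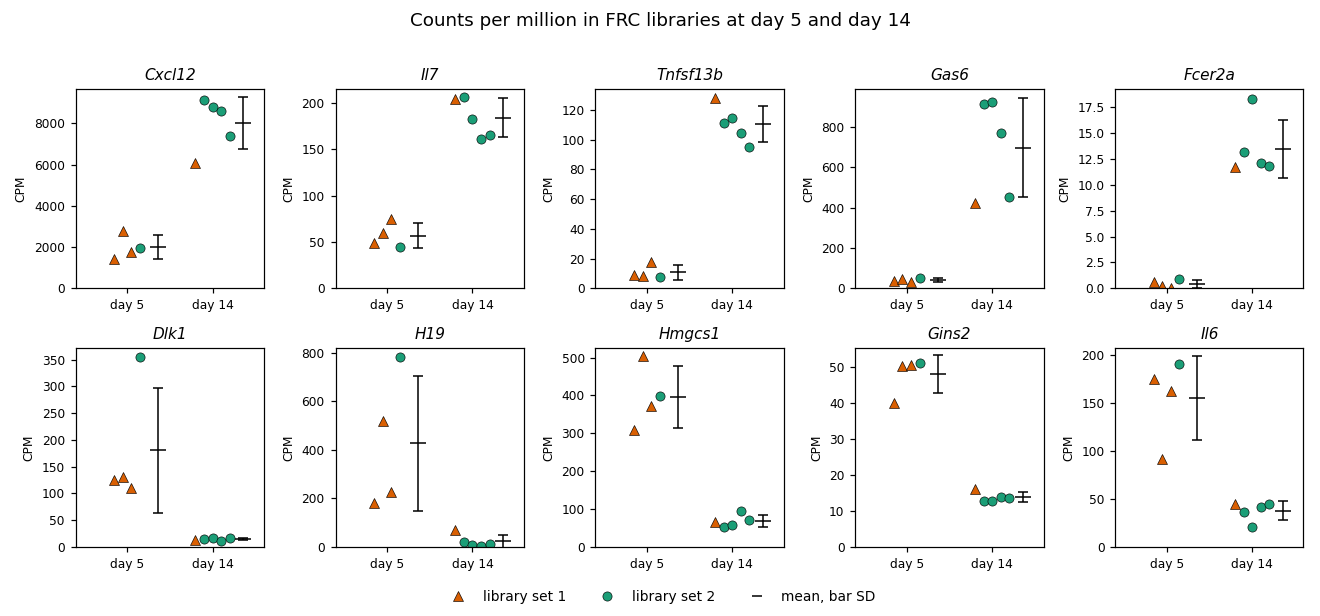
CPM of 10 genes in FRC libraries at day 5 (n = 4) and day 14 (n = 5), with triangles for library set 1, circles for library set 2, and a dash and bar for the mean and SD. Cxcl12, Il7, Tnfsf13b, Gas6 and Fcer2a are higher at day 14, and Dlk1, H19, Hmgcs1, Gins2 and Il6 are lower.

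Of the 18 measured FRC survival and chemokine genes, 11 rose, 1 fell and 6 did not pass (11 rose and 3 fell adjusted over the list alone). The 1 that fell was Il6, an inflammatory cytokine, from 155 ± 43.5 to 37.7 ± 9.73 CPM (-2.02 ± 0.26). The list had a camera adjusted p = 0.0043, and adjusted p = 0.29 with an estimated correlation. Genes of the lymphotoxin beta receptor and NF-kB organizer list had 5 rises and 1 fall among 18 members (6 and 1 adjusted over the list alone; camera adjusted p = 0.087). They included Mfge8, an opsonin for apoptotic cells, from 3568 ± 859 to 7998 ± 1607 CPM (1.18 ± 0.24), and Cr2, a complement receptor (2.91 ± 0.58, and 2.21 with adjusted p = 0.13 with library set as a term).

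Of 42 cell cycle genes, 34 fell and 0 rose (42 and 0 adjusted over the list alone), among them Gins2, a replication fork gene (-1.78 ± 0.18), Rrm2, a ribonucleotide reductase gene (-1.89 ± 0.25), Tyms (-1.28 ± 0.16) and Mcm2 (-1.22 ± 0.17). The list had a camera adjusted p = 3.3e-20, and adjusted p = 0.11 with an estimated correlation. Of 20 imprinted and fetal growth genes, 13 fell and 0 rose (15 and 0 adjusted over the list alone), with Mest (-3.04 ± 0.28), Rian (-2.37 ± 0.18) and Slc38a4 (-2.25 ± 0.25) beside Dlk1. Its camera adjusted p was 7.2e-11, and adjusted p = 0.11 with an estimated correlation.

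Genes of lipid and energy metabolism were among the falls as well. Of 24 genes of cholesterol synthesis and uptake, 18 fell and 0 rose (18 and 1 adjusted over the list alone), with Hmgcs1 from 396 ± 80.6 to 68.4 ± 16.2 CPM (-2.52 ± 0.21), Hmgcr, the rate-limiting enzyme of the pathway (-2.18 ± 0.20), Cyp51 (-2.51 ± 0.21) and Sqle (-2.71 ± 0.30). The camera adjusted p was 6.6e-14, and adjusted p = 0.076 with an estimated correlation. Of 37 oxidative phosphorylation genes, 15 fell and 0 rose (31 and 0 adjusted over the list alone). Oxidative phosphorylation genes had a camera adjusted p of 1.3e-10, and adjusted p = 0.35 with an estimated correlation. Uqcrc2 had -0.62 ± 0.15 and passed at adjusted p = 0.019 (0.0506, 0.0536 and 0.0574 without day 5 replicate 3, day 14 replicate 2 and day 14 replicate 4). The median log2 deviation of this list from the mean of the 9 FRC libraries was 0.42 to 0.65 in day 5 replicates 1 to 3 and -0.08 in day 5 replicate 4, and 0.23 in day 14 replicate 1 and -0.43 to -0.35 in day 14 replicates 2 to 5. With library set as a term 9 of its genes fell and the camera adjusted p was 3.8e-07.

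Part of the antigen presentation and lysosome lists rose. Of 18 class I genes 9 rose and 1 fell (9 and 1 adjusted over the list alone), with H2-D1 from 600.0 ± 110.3 to 1508 ± 214 CPM (1.35 ± 0.19), H2-K1 (1.04 ± 0.20) and H2-M3 (1.63 ± 0.22). The camera adjusted p was 0.0043, and adjusted p = 0.36 with an estimated correlation. Class II genes had 2 rises among 7 (3 adjusted over the list alone), Cd74 from 10.4 ± 5.68 to 47.9 ± 18.7 CPM (2.20 ± 0.37) and H2-Ab1 from 74.1 ± 25.3 to 152 ± 24.3 CPM (1.04 ± 0.25). That list had a camera adjusted p = 0.018, and adjusted p = 0.36 with an estimated correlation. Its call was lost without day 5 replicate 2 (0.0773) or day 5 replicate 4 (0.141), and that of H2-Ab1 without day 5 replicate 2 (0.0616) or day 14 replicate 3 (0.0554). Of 35 lysosome and phagocyte genes 11 rose and 0 fell (17 and 0 adjusted over the list alone), including the cathepsin genes Ctsl (1.25 ± 0.18) and Ctss (2.52 ± 0.42) and the cholesterol exporter Abca1 (2.29 ± 0.49). The camera adjusted p was 0.00034, and adjusted p = 0.29 with an estimated correlation.

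Inflammatory cytokine genes had 4 falls among 11 (5 adjusted over the list alone), including the neutrophil chemokine genes Cxcl1 (-1.33 ± 0.20) and Cxcl2 (-1.47 ± 0.26) and the monocyte chemokine Ccl2, from 3347 ± 1829 to 986 ± 781 CPM (-1.76 ± 0.55). The camera adjusted p was 0.049, with adjusted p = 0.36 with an estimated correlation, 0.13 with library set as a term, and 0.0624 to 0.248 without day 5 replicates 1, 2, 3 or 4 or day 14 replicates 1, 2 or 4. With library set as a term Ccl2 had -0.66 and adjusted p = 0.18, and without each other library than day 5 replicate 4 and day 14 replicate 1 its adjusted p was 0.0785 to 0.129. Among 28 immediate early and stress genes 5 fell and 0 rose (5 and 0 adjusted over the list alone; camera adjusted p = 0.15), with Klf6 at -1.07 ± 0.23. Interferon response genes had 3 falls among 36 (3 adjusted over the list alone; camera adjusted p = 0.11), among them Cxcl10 (-1.23 ± 0.26). The interferon list summed to 2796, 1086, 4249 and 1635 CPM in day 5 replicates 1 to 4 and to 1388 to 1831 CPM in the day 14 libraries. Collagen and matrix genes went both ways, 3 up and 4 down among 40 (5 and 4 adjusted over the list alone; camera adjusted p = 0.29). Timp1 (-1.75 ± 0.26), Col12a1 (-1.43 ± 0.28) and Vcan (-2.53 ± 0.50) fell. The median log2 deviation of the matrix list from the mean of the 9 libraries was -0.56 to 0.02 in day 5 replicates 1 to 3 and 0.58 in day 5 replicate 4, and -0.38 in day 14 replicate 1 and 0.18 to 0.31 in day 14 replicates 2 to 5.

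Lists of other cell types were measured in the same FRC libraries. Of 17 resident macrophage genes 4 rose and 0 fell (4 and 0 adjusted over the list alone). Resident macrophage genes had a camera adjusted p of 0.018, and adjusted p = 0.2 with an estimated correlation, and 0.0643 without day 5 replicate 4. They included Gas6, the lipid carrier Apoe, from 3792 ± 664 to 18118 ± 1200.3 CPM (2.27 ± 0.21) and Timd4, a phosphatidylserine receptor (1.60 ± 0.39; adjusted p = 0.0561 without day 5 replicate 3). Ptprc and Lyz2, abundant in macrophages, were at most 5.93 and 8.89 CPM in an FRC library. Of 5 B cell genes 4 rose and 1 fell (4 and 1 adjusted over the list alone), with Fcer2a, the low-affinity IgE receptor, from 0.443 ± 0.409 to 13.4 ± 2.79 CPM (5.07 ± 0.58), Blnk (3.13 ± 0.42), Ighm (2.55 ± 0.42) and Spib (1.43 ± 0.31). B cell genes had a camera adjusted p of 0.0049, and adjusted p = 0.11 with an estimated correlation. The summed level of the list did not rise, at 637 ± 75.4 CPM at day 5 and 562 ± 26.1 CPM at day 14. The endothelial list had 4 rises and 1 fall among 12 (camera adjusted p = 0.14), with Plvap at 1.22 ± 0.27. Pericyte and smooth muscle genes had 4 rises and 1 fall among 17 (camera adjusted p = 0.24), with Synpo2 up (2.06 ± 0.31) and Mcam down (-1.26 ± 0.18). Their median log2 deviation from the mean of the 9 libraries was -0.63 to -0.08 in day 5 replicates 1 to 3, 0.15 in day 5 replicate 4, -0.41 in day 14 replicate 1 and 0.12 to 0.65 in day 14 replicates 2 to 5. Adipocyte precursor genes had 2 rises and 3 falls among 15 (camera adjusted p = 0.37), with Pi16 up (2.75 ± 0.37) and Ebf2 down (-1.62 ± 0.27). These 3 lists had, adjusted over the list alone, 5 rises and 1 fall, 9 and 2, and 2 and 3. The T cell (1 rise among 6), dendritic cell (1 rise and 2 falls among 11), classical monocyte (1 fall among 7) and nonclassical monocyte (1 rise among 9) lists did not pass camera, with adjusted p of 0.37, 0.96, 0.37 and 0.52. Their counts adjusted over the list alone were 2 rises, 3 rises and 2 falls, 1 fall and 1 rise. The neutrophil, NK, erythroid and epithelial or muscle lists had 4, 1, 2 and 3 measured members, too few to test, with 0, 1, 1 and 1 falls and 0 rises.

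In Ly6C-high monocyte-macrophages, the genes that rose from day 5 to day 14 included members of the class II and interferon response lists. H2-Ab1, a class II chain, went from 915 ± 313 to 3778 ± 558 CPM (2.11 ± 0.20), and H2-Eb1 from 303 ± 94.1 to 1189 ± 105 CPM (2.04 ± 0.18). Ighm, the immunoglobulin mu heavy chain, went from 40.8 ± 7 to 179 ± 11.8 CPM (2.20 ± 0.15). Other large rises were in Clec2i (2.10 ± 0.32), Cbr2 (2.07 ± 0.48), Ms4a8a (2.04 ± 0.33), Ifit3b (2.18 ± 0.56) and the lectin gene Cd209a (4.65 ± 0.96; adjusted p = 0.0658 without day 14 replicate 2). Pf4 was 82.2-fold higher at day 5 (95% counting interval 14.3 to 3289, 75 against 1 counts) and Il1a 42.7-fold higher (11.4 to 359, 78 against 2 counts). Spint1, a protease inhibitor gene, went from 79.2 ± 15.6 to 3.81 ± 1.75 CPM (-4.17 ± 0.27), and Cd63 from 60.6 ± 12.4 to 5.91 ± 3.8 CPM (-3.11 ± 0.29). Tysnd1 (-3.28 ± 0.49), the calprotectin gene S100a8 (-2.98 ± 0.53; adjusted p = 0.0598 without day 14 replicate 2), Stfa1 (adjusted p = 0.049) and the iron exporter Slc40a1 (adjusted p = 0.043) fell too. The neutrophil list summed to 2069 CPM in day 5 replicate 2, 548 and 629 CPM in the other day 5 libraries and 478 to 575 CPM in the day 14 libraries. H2-Ab1 lies on chromosome 17, 34257689 to 34269419 and Spint1 on chromosome 2, 119237362 to 119249527.

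By edgeR, 1023 of 12876 genes passed, 434 higher and 589 lower at day 14, of which 482 changed at least 2-fold. Without day 5 replicates 1, 2 and 3 in turn the count was 643, 628 and 563, and in a fit of all 20 libraries it was 318. Of 77 named genes past the threshold, 58 passed without each library in turn, and Ifit3b (adjusted p of 0.0623 to 0.142 without day 5 replicates 1 and 3 and day 14 replicates 2 and 3), Stfa1 (0.055 to 0.131 without the same libraries) and Slc40a1 (0.06 to 0.117 without those and day 5 replicate 2) did not.

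Interferon response genes had the most rises by count of the lists tested in Ly6C-high cells, with 20 up and 0 down among 37 (29 and 0 adjusted over the list alone). By share, more of the class II list (7 of 11) and of the nonclassical monocyte list rose. Interferon response genes had a camera adjusted p of 5.3e-17, and adjusted p = 0.14 with an estimated correlation. Ifi47, an interferon-induced GTPase, had 1.50 ± 0.21, Oas3 1.16 ± 0.17, Irgm1 1.06 ± 0.17 and Stat2, a mediator of interferon signalling, 0.88 ± 0.14. Of the 20 genes that rose, 14 still rose without day 14 replicate 2. Markers of NK cells were uneven in the same libraries, and the NK list summed to 41.2 to 201 CPM at day 14 and 29.7 to 53.4 CPM at day 5. The NK list itself had 1 rise among 7, Klrk1 (1.31 ± 0.26), which was also the 1 adjusted over the list alone (camera adjusted p = 0.095). Of 11 class II genes 7 rose and 0 fell (7 and 1 adjusted over the list alone). Class II genes had a camera adjusted p of 3e-06, and adjusted p = 0.12 with an estimated correlation. Of 18 class I genes 6 rose (9 adjusted over the list alone), with H2-T23 at 1.19 ± 0.15. Class I genes had a camera adjusted p of 0.00032, and adjusted p = 0.14 with an estimated correlation.

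Monocyte genes that passed in Ly6C-high cells were nearly all higher at day 14, and macrophage genes that passed were more often lower. Of 20 classical monocyte genes 10 rose and 1 fell (12 and 1 adjusted over the list alone), with Ccr2, the receptor of Ccl2, from 1034 ± 14.5 to 1747 ± 58.1 CPM (0.83 ± 0.11) and Mgst1 (1.09 ± 0.17) up and Thbs1 (-1.60 ± 0.21) down. Classical monocyte genes had a camera adjusted p of 1e-05, and adjusted p = 0.12 with an estimated correlation. Of 19 nonclassical monocyte genes 12 rose and 1 fell (13 and 2 adjusted over the list alone), with Eno3 (1.52 ± 0.14) and Ace (1.06 ± 0.15) as examples. Nonclassical monocyte genes had a camera adjusted p of 1.9e-06, and adjusted p = 0.14 with an estimated correlation. Of 29 resident macrophage genes 9 fell and 3 rose (14 and 4 adjusted over the list alone). Resident macrophage genes had a camera adjusted p of 7.8e-05, and adjusted p = 0.14 with an estimated correlation. The adhesion molecule gene Vcam1 (-2.01 ± 0.23) and the macrophage transcription factor genes Mafb (-1.18 ± 0.15) and Spic (-1.12 ± 0.14) fell, and Apoe rose (1.13 ± 0.14). Of 22 cholesterol genes 7 fell (8 adjusted over the list alone), with Cyp51 at -1.43 ± 0.25 and Ldlr, the LDL receptor gene, at -0.82 ± 0.16. Cholesterol genes had a camera adjusted p of 2.2e-06, and adjusted p = 0.12 with an estimated correlation.

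Smaller groups also passed camera in Ly6C-high cells. The NF-kB organizer list had 6 falls among 17 (6 adjusted over the list alone), with Tnfaip3 at -1.02 ± 0.18. Organizer genes had a camera adjusted p of 0.0021, and adjusted p = 0.12 with an estimated correlation. The adipocyte list had 4 rises among 11 (6 adjusted over the list alone), including Pparg, a lipid-sensing nuclear receptor gene (1.47 ± 0.19), Dpp4 (0.92 ± 0.17) and the fatty acid transporter Cd36 (1.82 ± 0.33). Adipocyte list genes had a camera adjusted p of 0.015, and adjusted p = 0.12 with an estimated correlation. Inflammatory cytokine genes had 2 rises and 5 falls among 23 (3 and 6 adjusted over the list alone), with Osm (-1.10 ± 0.20) and Il1rn (-0.92 ± 0.18) down. Inflammatory cytokine genes had a camera adjusted p of 0.015, and adjusted p = 0.22 with an estimated correlation, and 0.132 without day 14 replicate 3. The imprinted list had 3 falls among 11 (5 adjusted over the list alone), and the matrix list 1 among 30 (1 adjusted over the list alone). Imprinted genes had a camera adjusted p of 0.019, and adjusted p = 0.22 with an estimated correlation, 0.072 without day 5 replicate 2 and 0.0635 without day 14 replicate 1. Matrix genes had a camera adjusted p of 0.0021, and adjusted p = 0.41 with an estimated correlation, and 0.0527 without day 14 replicate 1. Immediate early genes had 8 rises and 1 fall among 28, with Jun at 1.25 ± 0.14, and lysosome genes 6 rises and 6 falls among 36, with Abcg1 up (1.81 ± 0.14) and Ctsd down (-0.89 ± 0.12). These were, adjusted over the list alone, 8 and 5, and 7 and 8. Neither passed camera (adjusted p of 0.086 and 0.82), and nor did the cell cycle (2 falls among 42; 0.23), oxidative phosphorylation (0 of 37 by edgeR, and 1 higher and 1 lower at an unadjusted p under 0.05; 0.98), FRC survival (1 of 13 rose; 0.63), dendritic cell (3 rises and 3 falls among 20; 0.5), neutrophil (2 falls among 10; 0.063), T cell (1 of 13 rose; 0.7), B cell (1 rise and 2 falls among 9; 0.063), endothelial (2 of 9 rose; 0.13) and pericyte (1 of 8 fell; 0.17) lists. In the same order, the counts adjusted over the list alone were 0 rises and 1 fall, 0 and 0, 0 and 0, 3 and 3, 2 and 3, 1 and 0, 1 and 4, 2 and 0, and 0 and 3.

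In Ly6C-low monocyte-macrophages, day 14 was compared with day 5 in the same way. H2-Eb1 went from 822 ± 9.39 to 3012 ± 633 CPM (1.89 ± 0.19), H2-Ab1 from 1973 ± 133 to 6853 ± 1097 CPM (1.81 ± 0.21) and H2-Aa from 1255 ± 54.8 to 4362 ± 941 CPM (1.81 ± 0.19). Ly6c2, the gene behind the sort marker, went from 6 ± 1.52 to 27.1 ± 10 CPM (2.17 ± 0.27), and Ccr2 from 374 ± 39.3 to 865 ± 37.8 CPM (1.22 ± 0.12). Spint1 fell from 42.2 ± 6.27 to 10 ± 0.578 CPM (-2.05 ± 0.28). Galnt9, Mfge8, Ndrg1 and Ly6a2 rose, and Hgsnat, Eva1b, Htra3, the complement gene C2, Cyth2, Rps4l and Ppp4c fell, with log2 changes of 2.32, 1.91, 1.73, 1.50, -1.95, -1.76, -1.66, -1.59, -1.59, -1.59 and -1.41. These 11 calls did not stand without each library: 4 were lost without day 5 replicate 1 (adjusted p of 0.0875 to 0.11), 8 without day 5 replicate 2 (0.0602 to 0.161), 10 without day 14 replicate 1 (0.0565 to 0.457) and 9 without day 14 replicate 2 (0.0651 to 0.397). Mfge8 had 122 CPM in day 14 replicate 1 and 34.3 CPM in replicate 2. The same replicate 1 held 151.6 CPM of the haemoglobin gene Hbb-bs and an erythroid list sum of 244 CPM, against 12.8 CPM in replicate 2.

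With 2 libraries at day 14, edgeR called 210 of 12876 genes by adjusted p, 140 higher and 70 lower, and 109 changed at least 2-fold. The count was 129, 74 and 324 without day 5 replicates 1, 2 and 3, and 93 and 36 without day 14 replicates 1 and 2. It was 474 by DESeq2, 400 by limma-voom, 467 with no low-count filter and 10 in a fit of all 20 libraries, and 13 of 46 named genes passed without each library in turn.

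Of 11 class II genes 7 rose in Ly6C-low cells (7 adjusted over the list alone), including Cd74 (1.35 ± 0.15). Class II genes had a camera adjusted p of 9.9e-11, and adjusted p = 0.071 with an estimated correlation. Of 20 classical monocyte genes 9 rose (12 rose and 2 fell adjusted over the list alone), with Mgst1 (1.47 ± 0.20) beside Ccr2 and Ly6c2, and of 19 nonclassical genes 4 rose (8 adjusted over the list alone), with Pglyrp1 (1.28 ± 0.16), Ace (1.19 ± 0.17) and Ear2 (1.24 ± 0.18). Classical monocyte genes had a camera adjusted p of 4.4e-08, and adjusted p = 0.071 with an estimated correlation. Nonclassical monocyte genes had a camera adjusted p of 4.4e-06, and adjusted p = 0.24 with an estimated correlation. Cholesterol genes had 3 falls among 22 (11 adjusted over the list alone), Ldlr (-1.10 ± 0.19), Sqle (-2.55 ± 0.51) and Mvd (-0.96 ± 0.22), and without day 14 replicate 2 their adjusted p was 0.15, 0.291 and 0.39. Cholesterol genes had a camera adjusted p of 2.2e-09, and adjusted p = 0.071 with an estimated correlation. Cell cycle genes had 2 falls among 42 (15 adjusted over the list alone), and the imprinted list 1 among 11 (3 adjusted over the list alone), H19 (-4.95 ± 0.80; adjusted p = 0.0606 without day 14 replicate 1). Cell cycle genes had a camera adjusted p of 4e-13, and adjusted p = 0.24 with an estimated correlation. Imprinted genes had a camera adjusted p of 1.1e-05, and adjusted p = 0.071 with an estimated correlation.

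The other 7 lists past camera in Ly6C-low cells each held at most 4 called genes and were lost without at least 1 library. Interferon response had 1 rise among 37, Oas3 (1.07 ± 0.20; camera adjusted p = 0.0079, adjusted p = 0.65 with an estimated correlation, 0.517 without day 5 replicate 1 and 0.323 without day 14 replicate 1). Class I had 1 rise among 18 (0.0079; adjusted p = 0.31 with an estimated correlation, 0.0555 without day 14 replicate 1). Inflammatory cytokines had 1 fall among 23, Il18 (-0.66 ± 0.13; 0.02; adjusted p = 0.31 with an estimated correlation, 0.0937 without day 5 replicate 2 and 0.111 without day 14 replicate 1). Oxidative phosphorylation had 0 calls among 37 by edgeR (2 at an unadjusted p under 0.05; 0.014; adjusted p = 0.66 with an estimated correlation, 0.0838 without day 5 replicate 3 and 0.292 without day 14 replicate 2). Resident macrophage genes had 1 rise and 2 falls among 29, with Hmox1, haem oxygenase, at -1.18 ± 0.20 (0.0082; adjusted p = 0.33 with an estimated correlation, 0.228 without day 14 replicate 2). The lysosome list had 2 rises and 2 falls among 36 (0.0498; adjusted p = 0.43 with an estimated correlation, and 0.0574, 0.102, 0.0609 and 0.217 without day 5 replicates 2 and 3 and day 14 replicates 1 and 2). T cell genes had 0 calls among 13 by edgeR (3 at an unadjusted p under 0.05; 0.0011; adjusted p = 0.31 with an estimated correlation, 0.0736 without day 14 replicate 1), and their sum was 446 CPM in day 14 replicate 1 and 294 CPM in replicate 2. The same 7 lists had, adjusted over the list alone, 2 interferon rises, 1 class I rise, 1 cytokine fall, 0 oxidative phosphorylation falls, 2 rises and 8 falls of resident macrophage genes, 3 and 5 of lysosome genes, and 0 T cell rises. The other 11 lists tested did not pass camera, with adjusted p from 0.13 for B cell genes to 0.8 for neutrophil genes.

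Between the gates, 82 genes rose with age in both and 39 fell in both, against 4.72 and 3.20 expected if the calls were independent, and 0 went opposite ways. The 2 age comparisons share no library, and both come from 1 fit. FRC and Ly6C-low cells shared 24 rises and 15 falls (5.32 and 5.08 expected), whereas FRC and Ly6C-high cells shared 44 rises and 33 falls (22.6 and 43.5 expected), and 60 genes rose in FRC and fell in Ly6C-high cells (36.2 expected). The FRC calls here came from the fit without library set as a term, which kept 65.4% of them. The overlaps were not counted with that term.

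**Figure D3:**
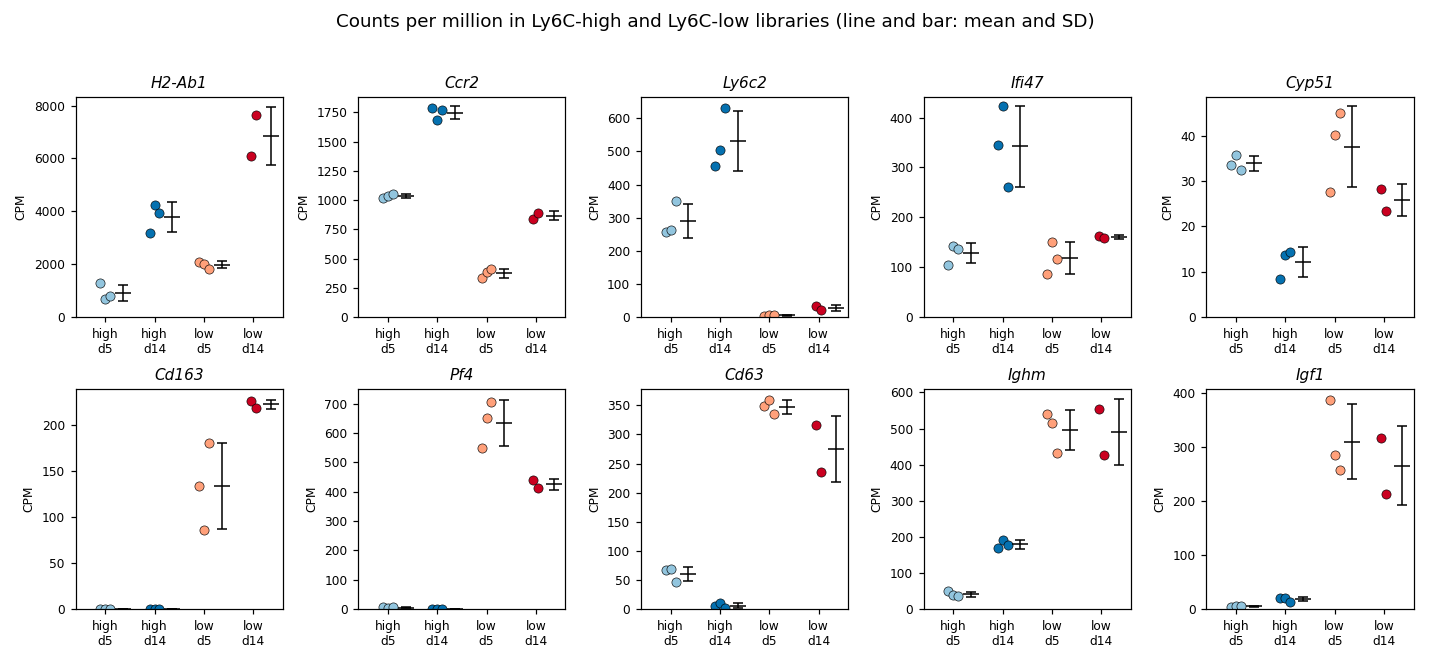
CPM of 10 genes in the Ly6C-high and Ly6C-low libraries at day 5 and day 14, each point 1 library, with a dash and bar for the mean and SD (n = 3, 3, 3 and 2). H2-Ab1 is higher at day 14 in both gates, and Cd163 and Pf4 are higher in Ly6C-low cells at both ages.

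The comparison of the gates at day 5 asked how Ly6C-low cells differed from Ly6C-high cells. Genes higher in Ly6C-low cells included Cd163 and Lyve1 of the resident macrophage list and Siglech of the dendritic cell list. Cd163, a scavenger receptor for haemoglobin, was 2027-fold higher (95% counting interval 363 to 80107, 1882 against 1 counts), Lyve1, a hyaluronan receptor, 1881-fold (337 to 74321), Cd209f 4093-fold (734 to 161704), Siglech 573-fold (196 to 2780) and Adam33 433-fold (119 to 3581). Ccl8 had 0 counts in Ly6C-high cells and was at least 189.6-fold higher, against a floor of 3 counts over the group. Ednrb had 383 ± 77.2 against 0.615 ± 0.275 CPM (Ly6C-low over Ly6C-high 9.23 ± 0.30) and the ficolin gene Fcna 8.64 ± 0.47. Ly6c2 (-5.64 ± 0.25), Vcan (-6.11 ± 0.32), Ly6a2 (-5.36 ± 0.23), Stfa3 (-6.86 ± 0.56) and S100a8 (-7.71 ± 0.76) were lower in Ly6C-low cells. S100a9 was 1730-fold (310.1 to 68355) and Stfa1 956-fold (171 to 37807) higher in Ly6C-high cells, and Cd177 at least 112-fold, and without each of the 3 Ly6C-low libraries in turn the adjusted p of these genes was 0.0513 to 0.178. Ly6C-high day 5 replicate 2 stood apart in them, with 369 CPM of S100a9, 151 of Stfa1 and 65.2 of Cd177, against at most 22.5, 36.2 and 7.39 CPM in the other Ly6C-high libraries of that age. Without replicate 2 the 3 genes still passed, with smaller differences. Cd163 lies on chromosome 6, 124304656 to 124330527 and Ly6c2 on chromosome 15, 75108158 to 75111970.

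By edgeR, 2081 of 12876 genes passed at day 5, 1167 higher and 914 lower in Ly6C-low cells, of which 1117 differed at least 2-fold. In a fit of all 20 libraries the count was 1231, and 74 of 85 named genes passed without each library in turn.

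Of 29 resident macrophage genes 26 were higher and 0 lower in Ly6C-low cells at day 5 (26 and 0 adjusted over the list alone), with Pf4 at 6.98 ± 0.25, Selenop at 3.36 ± 0.14, Cbr2 at 7.74 ± 0.34 and Apoe at 2.75 ± 0.14. Resident macrophage genes had a camera adjusted p of 2.8e-26, and 0.0066 with an estimated correlation. Of 20 classical monocyte genes 18 were lower and 1 higher (19 and 1 adjusted over the list alone), with Hp, haptoglobin, at -2.99 ± 0.16. Classical monocyte genes had a camera adjusted p of 3.1e-20, and 0.0063 with an estimated correlation. These 2 lists kept their call with an estimated correlation. B cell genes were higher, 6 of 9 (6 adjusted over the list alone), with Ighm at 3.52 ± 0.16 and Cd22 at 2.82 ± 0.31. B cell genes had a camera adjusted p of 0.00025, and adjusted p = 0.066 with an estimated correlation. Dendritic cell genes were higher in 8 of 20 (8 adjusted over the list alone), with the lectin Clec10a at 3.36 ± 0.20. Dendritic cell genes had a camera adjusted p of 0.0074, and adjusted p = 0.11 with an estimated correlation. Lysosome genes were higher in 13 and lower in 2 of 36 (15 and 2 adjusted over the list alone), with the protease Lgmn at 2.07 ± 0.12. Lysosome genes had a camera adjusted p of 0.0012, and adjusted p = 0.21 with an estimated correlation. Inflammatory cytokine genes were higher in 9 and lower in 4 of 23 (10 and 5 adjusted over the list alone), with Ccl2 at 5.02 ± 0.27 and Il18 at 1.74 ± 0.12. Inflammatory cytokine genes had a camera adjusted p of 0.0077, and adjusted p = 0.21 with an estimated correlation. Neutrophil genes were lower in 5 of 10 (6 adjusted over the list alone), with Mmp8 at -3.70 ± 0.28. Neutrophil genes had a camera adjusted p of 0.00074, and adjusted p = 0.19 with an estimated correlation. The list summed to 2069 CPM in Ly6C-high day 5 replicate 2, against 629 and 548 CPM in replicates 1 and 3, and passed camera without replicate 2. Cell cycle genes were higher in 8 of 42 (13 adjusted over the list alone), with Mcm2 at 1.47 ± 0.25. Cell cycle genes had a camera adjusted p of 0.0012, and adjusted p = 0.59 with an estimated correlation.

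Further lists differed between the gates at day 5 with few members past the test. The adipocyte list had 5 higher and 1 lower of 11 (camera adjusted p = 0.0052, and adjusted p = 0.076 with an estimated correlation), with Cd36 at 3.77 ± 0.34 and Pi16 at -2.21 ± 0.16, and the imprinted list 2 higher of 11 (0.0081; adjusted p = 0.21 with an estimated correlation), with H19 at 4.52 ± 0.65. Interferon genes were lower in 10 and higher in 2 of 37 (0.0077; adjusted p = 0.64 with an estimated correlation, 0.0583 without Ly6C-high replicate 2 and 0.227 without Ly6C-low replicate 1), with Oas3 at -1.50 ± 0.18. Oxidative phosphorylation genes were lower in 2 of 37 (0.0074; adjusted p = 0.64 with an estimated correlation, 0.127 without Ly6C-high replicate 1). The matrix list had 4 higher and 2 lower of 30 (0.039; adjusted p = 0.64 with an estimated correlation, and 0.0702, 0.0583 and 0.331 without Ly6C-high replicates 1 and 2 and Ly6C-low replicate 1), and the endothelial list 2 higher and 1 lower of 9 (0.032; adjusted p = 0.21 with an estimated correlation, and 0.0657, 0.0804 and 0.0767 without Ly6C-high replicate 2 and Ly6C-low replicates 1 and 2), with Pecam1 at 1.48 ± 0.18. Adjusted over the list alone, these 6 lists had 5 higher and 1 lower, 3 higher, 3 and 10, 1 lower, 4 and 2, and 3 and 1. The T cell list had 2 higher of 13 (2 adjusted over the list alone; camera adjusted p = 0.27), Cd4 (3.93 ± 0.38), which is also transcribed in macrophages, and Cd28, and summed to 260 to 394 CPM in Ly6C-low and 41.2 to 60.6 CPM in Ly6C-high cells. The other 9 lists tested did not pass, with adjusted p from 0.084 for class II genes to 0.66 for cholesterol genes. They included nonclassical monocyte genes, higher in 4 and lower in 7 of 19 (4 and 8 adjusted over the list alone; 0.55).

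At day 14 genes of the resident macrophage list, Cd163, Folr2, Cd5l and Pf4 among them, again stood far above their levels in Ly6C-high cells. With 0 counts in Ly6C-high cells, Cd163 was at least 1258-fold higher in Ly6C-low cells, Cd209f at least 1657-fold, Retnla at least 6315-fold, the folate receptor gene Folr2 at least 435-fold, Colq at least 298-fold and Cd5l at least 149-fold. Pf4 was 7241-fold higher (95% counting interval 1299 to 286075, 4313 against 1 counts) and Ednrb 1250.2-fold (427 to 6067). Ly6c2 (-4.41 ± 0.25), Vcan (-5.20 ± 0.35), Mmp8 (-4.65 ± 0.34), Ly6a2 (-4.21 ± 0.24), Stfa3 (-4.11 ± 0.70), the fibronectin gene Fn1 (-4.01 ± 0.53), Slfn4 (-3.38 ± 0.35) and S100a8 (-4.53 ± 0.90) were lower in Ly6C-low cells, the last with an adjusted p of 0.13 without Ly6C-low replicate 1 and 0.0844 without Ly6C-low replicate 2. Of the genes called at both ages, 710 were higher and 497 lower in Ly6C-low cells each time (93.4 and 59.8 expected if independent), and 4 went opposite ways.

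By edgeR, 1874 of 12876 genes passed at day 14, 1031 higher and 843 lower in Ly6C-low cells, of which 1032 differed at least 2-fold. The count was 886 and 1212 without Ly6C-low replicates 1 and 2, 1059 in a fit of all 20 libraries and 1241 in a fit of the 2 groups alone, and 56 of 87 named genes passed without each library in turn.

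Of 29 resident macrophage genes 26 were higher and 0 lower in Ly6C-low cells at day 14 (26 and 0 adjusted over the list alone), with Selenop at 2.81 ± 0.14. Resident macrophage genes had a camera adjusted p of 3.7e-27, and 0.0059 with an estimated correlation. Of 20 classical monocyte genes 16 were lower and 1 higher (18 and 1 adjusted over the list alone). Classical monocyte genes had a camera adjusted p of 2.5e-18, and 0.0059 with an estimated correlation. B cell genes were higher in 5 of 9 (7 adjusted over the list alone), with Cd22 at 3.48 ± 0.38, and dendritic cell genes in 7 of 20 (8 adjusted over the list alone), with Fscn1 at 4.35 ± 0.35. B cell genes had a camera adjusted p of 2e-05, and 0.04 with an estimated correlation. Dendritic cell genes had a camera adjusted p of 0.00029, and 0.04 with an estimated correlation. These 4 lists kept their call with an estimated correlation. Interferon response genes were lower in 20 of 37 (26 adjusted over the list alone), with Oas3 at -1.60 ± 0.20 and Zbp1 at -1.44 ± 0.19. Interferon response genes had a camera adjusted p of 1.1e-12, and adjusted p = 0.27 with an estimated correlation. Oxidative phosphorylation genes were lower in 5 of 37 (5 adjusted over the list alone). Oxidative phosphorylation genes had a camera adjusted p of 2e-05, and adjusted p = 0.46 with an estimated correlation. Inflammatory cytokine genes were higher in 9 and lower in 5 of 23 (10 and 5 adjusted over the list alone), with Ccl7 865-fold (296 to 4200.0) and Il1a 488-fold (134 to 4037) higher. Inflammatory cytokine genes had a camera adjusted p of 0.0058, and adjusted p = 0.27 with an estimated correlation.

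The remaining lists past camera at day 14 were lost without at least 1 library. Matrix genes were higher in 9 and lower in 2 of 30 (0.0012; adjusted p = 0.46 with an estimated correlation, 0.166 without Ly6C-low replicate 1). Cell cycle genes were lower in 9 and higher in 3 of 42 (0.014; adjusted p = 0.54 with an estimated correlation, 0.0687 and 0.151 without Ly6C-high replicates 2 and 3). T cell genes were higher in 3 of 13 (0.0058; adjusted p = 0.34 with an estimated correlation, 0.101 without Ly6C-low replicate 1), class II genes in 3 of 11 (0.017; adjusted p = 0.39 with an estimated correlation, 0.133 without Ly6C-low replicate 2), and the neutrophil list had 2 higher and 4 lower of 10 (0.015; adjusted p = 0.34 with an estimated correlation, 0.0774 without Ly6C-high replicate 1 and 0.0568 without Ly6C-low replicate 2). Adjusted over the list alone, these 5 lists had 12 higher and 2 lower, 3 and 14, 5 and 1, 5 and 0, and 2 and 4. The other 12 lists tested did not pass, with adjusted p from 0.075 for lysosome genes (10 higher and 2 lower of 36; 13 and 5 adjusted over the list alone) to 0.97 for immediate early genes.

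The test of whether the age change differed between the gates singled out a short list. Cd63 fell in Ly6C-high cells from 60.6 to 5.91 CPM and had 348 and 275 CPM in Ly6C-low cells (difference 2.79 ± 0.39; adjusted p = 0.0673 without Ly6C-low day 14 replicate 1). Pf4 had 4.65 and 0.12 CPM in Ly6C-high cells and 634 and 426 CPM in Ly6C-low cells (adjusted p = 0.0771 without Ly6C-high day 14 replicate 2), and Dst 12 and 1.82, against 62.2 and 61.6 CPM (0.0526 without Ly6C-low day 14 replicate 1). Ighm rose in Ly6C-high cells from 40.8 to 179 CPM and had 496 and 491 CPM in Ly6C-low cells (difference -2.20 ± 0.22), and it kept its call without each library. Igf1, insulin-like growth factor 1, had 5.34 and 18.3 CPM in Ly6C-high and 309.8 and 266 CPM in Ly6C-low cells (difference -2.10 ± 0.31; adjusted p = 0.055 without Ly6C-high day 5 replicate 1). Spint1 (2.12), Olr1 (2.16), Vcam1 (1.73), F13a1 (-1.46) and Jun (-1.16) also passed, and each call was lost without 5 to 7 of the 11 libraries in turn (adjusted p of 0.0526 to 0.186), Ly6C-high day 5 replicate 2 and Ly6C-low day 14 replicate 1 being common to the 5 genes. Of 42 cell cycle genes and 37 interferon genes, 0 of either list passed by edgeR over all genes, with 18 and 15 lower in Ly6C-low cells at an unadjusted p under 0.05. Adjusted over the list alone the counts lower were 12 and 13. Camera gave adjusted p = 1.9e-12 and 6.8e-10, with adjusted p = 0.62 and 0.62 with an estimated correlation. The other 22 lists had adjusted p from 0.055 to 0.75. The count of 2 lists was not stable, at 2 to 8 without each library in turn (8 without Ly6C-low day 14 replicate 2), 5 with replicate number as a block, and 0 with fry or an estimated correlation.

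By edgeR, 18 of 12876 genes differed in their age change, 14 higher and 4 lower in Ly6C-low cells, and 1070 had an unadjusted p under 0.05. The count was 92 by DESeq2, 8 by limma-voom, 134 with no low-count filter and 4 in a fit of all 20 libraries, and 10, 11, 10, 49 and 5 without Ly6C-high day 5 replicates 1 and 2, Ly6C-low day 5 replicate 1, Ly6C-high day 14 replicate 1 and Ly6C-low day 14 replicate 1.

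The last comparison asked where the age change of FRC differed from the mean age change of the monocyte-macrophage gates. It was lower in FRC for Msmo1 at -2.67 ± 0.37, Hmgcs1 at -1.69 ± 0.28 and Cyp51 at -1.58 ± 0.29, genes of cholesterol synthesis (FRC less monocyte-macrophages). Batf3, a transcription factor gene, went from 12.1 ± 1.92 to 2.78 ± 0.608 CPM in FRC and from 17.5 to 23.4 CPM in Ly6C-high cells (-2.52 ± 0.33). Ctsl (1.65 ± 0.20), Lamp1 (2.34 ± 0.39), Slc40a1 (3.36 ± 0.57) and Spib (2.42 ± 0.35) had a higher age change in FRC. Slc40a1 rested on 6.23 and 12.2 CPM in FRC against 764 and 185 CPM in Ly6C-low cells. The genes with the largest differences were near 0 in one lineage, so levels are given without a fold. Zfhx4 had 59.1 and 127 CPM in FRC, Mme, the neprilysin gene, 34.6 and 119, Ephb4 45.9 and 58.4, Aldh3a1 22.6 and 66.3, and Smoc2 47.6 and 115 CPM, with at most 1.49 CPM in a monocyte-macrophage group mean. Clec7a, a receptor for fungal glucans, Ly6c2, Slfn4, Ifi209 and Trem3 had at most 0.957 CPM in an FRC group mean, and 1044 and 1006, 289.7 and 531, 47 and 79.8, 183 and 399, and 197 and 136 CPM in Ly6C-high cells at day 5 and day 14. Mme, Clec7a and Ifi209 kept their call without each library, whereas Zfhx4 had an adjusted p of 0.0668 without Ly6C-low day 5 replicate 1, Ly6c2 0.365 without FRC day 5 replicate 3, and the other 5 were lost without 4 to 10 of the 20 libraries in turn.

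By edgeR, 1269 of 16686 genes passed, 706 higher and 563 lower, of which 1062 differed at least 2-fold. With the FRC library set as a term the count was 871, 577 higher and 294 lower, and by DESeq2 and limma-voom it was 2393 and 4226. It was 832, 731, 625, 772, 719, 747 and 777 without Ly6C-high day 5 replicate 3, Ly6C-low day 14 replicates 1 and 2, FRC day 5 replicate 3 and FRC day 14 replicates 2, 3 and 4, and 3112 and 2915 without FRC day 5 replicate 4 and FRC day 14 replicate 1. Of 76 named genes past the threshold, 36 passed without each library in turn.

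By list, the age change of FRC was lower than that of monocyte-macrophages in cholesterol (8 of 24 genes), cell cycle (6 of 42; 2.9e-07; adjusted p = 0.26 with an estimated correlation), oxidative phosphorylation (3 of 37; 1.5e-08; adjusted p = 0.34 with an estimated correlation) and interferon response genes (10 of 37; 6.3e-06; adjusted p = 0.34 with an estimated correlation). Cholesterol genes had a camera adjusted p of 2.8e-06, and adjusted p = 0.069 with an estimated correlation. Classical and nonclassical monocyte genes (5 of 20 and 3 of 19; 0.0031 and 0.014; adjusted p = 0.069 and 0.2 with an estimated correlation), imprinted genes (1 of 20; 0.0039; adjusted p = 0.26 with an estimated correlation) and immediate early genes (4 down and 1 up of 28; 0.035; adjusted p = 0.34 with an estimated correlation) went the same way. Higher changes in FRC were found in resident macrophage (10 of 29; 7.2e-06; adjusted p = 0.069 with an estimated correlation), lysosome (11 of 36; 9.6e-06; adjusted p = 0.2 with an estimated correlation), B cell (4 of 11; 0.0016; adjusted p = 0.069 with an estimated correlation), NF-kB organizer (3 up and 1 down of 19; 0.0033; adjusted p = 0.069 with an estimated correlation) and matrix genes (2 up and 1 down of 40; 0.0057; adjusted p = 0.45 with an estimated correlation). Adjusted over the list alone, the downward counts were 9 cholesterol, 9 cell cycle, 23 oxidative phosphorylation, 19 interferon, 6 classical monocyte, 4 nonclassical monocyte, 3 imprinted and 10 immediate early genes, and the upward counts were 11 resident macrophage, 16 lysosome, 4 B cell, 3 organizer and 3 matrix genes. The matrix call was lost without Ly6C-low day 14 replicate 2 (0.0856), and the immediate early call without 7 libraries in turn (0.0501 to 0.0846): Ly6C-high day 5 replicate 1 and day 14 replicate 3, Ly6C-low day 5 replicate 1 and day 14 replicate 2, FRC day 5 replicate 2 and FRC day 14 replicates 3 and 4. In FRC the matrix list went with the library sets and did not rise within either. Its median log2 deviation in set 1 was -0.56 to 0.02 at day 5 and -0.38 at day 14. In set 2 it was 0.58 at day 5 and 0.18 to 0.31 at day 14. Of the classical monocyte, nonclassical monocyte, resident macrophage and B cell lists, 7, 9, 17 and 5 members passed the low-count filter in FRC alone. Their other members had low counts in FRC, where an age change is poorly measured. The lists of this comparison were not tested with library set as a term. The other 12 lists tested did not pass camera, with adjusted p from 0.083 for the survival and chemokine list to 0.99 for dendritic cell genes.

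**Figure D4:**
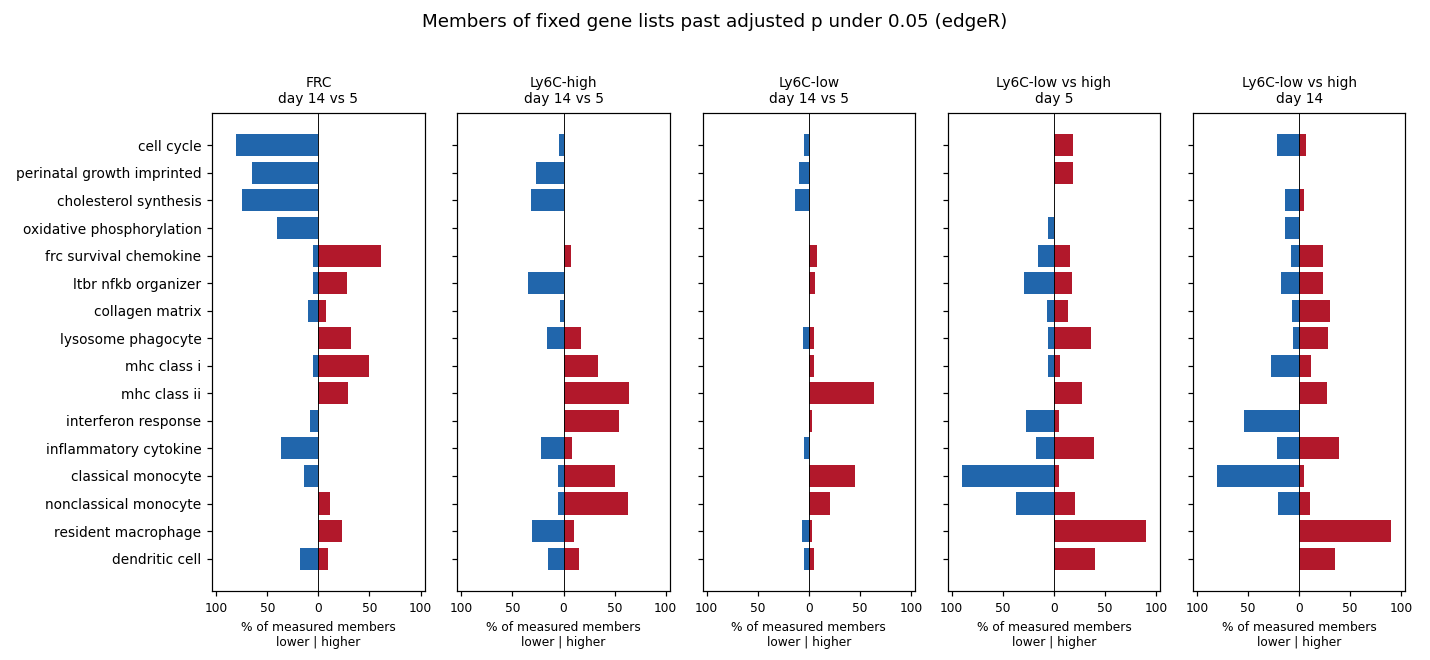
Percent of the measured members of 16 gene lists that were lower (blue, to the left) or higher (red, to the right) past the edgeR threshold in each of 5 comparisons, with bars starting at 0. Cell cycle and cholesterol genes lie to the left in FRC and class II genes to the right in both monocyte-macrophage gates at day 14.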

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

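The test for swapped labels was chosen only after the result was seen, whereas the length and GC, depth and regrouping tests were planned before their outcome was seen. The division that the length and GC and the depth tests concern was itself found in the data. A value was singled out where 1 library of an FRC group lay far from the others, at a threshold that chance passes in about 1 in 20 groups. Of 80 values tested 9 passed, with 4 expected.

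At day 5, replicate 4 had the highest Pdgfra, 610.0 CPM (229 in the next library), and the highest Dlk1, 355 CPM (131), and replicate 3 the highest Tnfsf13b, 18 CPM (8.72). At day 14, replicate 1 had the highest Pdpn, 545 CPM (225), the lowest Pdgfra, 302 CPM (756), the highest Cxcl13, 1320.3 CPM (835) and the highest H19, 71.3 CPM (19.4). Replicate 5 had the lowest Igfbp2, 14.5 CPM (64.8), and replicate 4 the lowest AW551984, 0.685 CPM (4.36).

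Of these 9 values, 6 came from day 5 replicate 4 and day 14 replicate 1, each the 1 library of its age in the other library set, and that division took up 43.5% of the variance left within the ages. Transcript length and GC bias may contribute but did not account for the whole division, which took up 39.98% of that variance after a trend on both was removed from each library (36.8% for the next division), and depth did not either, at 44.2% after thinning to equal totals (40.1% for the next). The first component of the variation within the ages held 47% of that variance. Across genes it correlated with transcript length at Spearman rho 0.36 and with GC content at 0.11. The division is also the grouping that swapped labels of day 5 replicate 4 and day 14 replicate 1 would produce. A swap would place each nearer the other age in nearly all genes that separate the remaining libraries. In 837 genes called at 4-fold or more without them, day 5 replicate 4 lay nearer day 5 in 44.7% and day 14 replicate 1 nearer day 14 in 49.2%. This argues against a swap, although each lay nearer the other age in the rest of these genes. The remaining libraries differ in set as well as age, so the 837 genes mix both. A difference in sort day, handling or library preparation stays open, since the labels name no batch, and no biological explanation was tested. Of 11 genes of other cell types Cd74 was the highest in either set, at up to 36.6 CPM in set 1 and 80.4 CPM in set 2.

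When the 9 FRC libraries were regrouped by chance, 3 of 100 splits, the real one included, gave at least the real 2216 genes. That share treats the 9 libraries as exchangeable, which the library sets contradict, and splits that keep the sets are too few for a share under 0.05. The highest other split gave 5083 genes, more than the ages did, and was the division into library sets, a structure of the samples that is spread unevenly over the ages. With library set as a term the age count was 1939. For Ly6C-high cells by age (1023 genes, highest other 1) and for the gates at day 5 (2081 genes, highest other 0), 1 of 10 splits reached the real count, and 10 splits are too few for a share under 0.05.

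The age change differed between groups by the test of the difference itself in 18 genes between the Ly6C gates and in 2 gene lists, cell cycle and interferon response, each with adjusted p = 0.62 with an estimated correlation and neither called by fry. The adjusted p was 0.00793 for Pf4 and for Cd63, 0.00532 for Dst, 0.0245 for Olr1, Spint1 and Jun, 8.01e-05 for Ighm, 0.0074 for Igf1 and 0.018 for F13a1. Between FRC and monocyte-macrophages it differed in 1269 genes and 13 lists, of which 0 were called with an estimated correlation and 11 by fry. The adjusted p was 0.0104 for Zfhx4, 0.00798 for Mme, 0.0328 for Ephb4, 0.0332 for Aldh3a1, 0.0203 for Smoc2, 0.00148 for Clec7a, 0.0113 for Ly6c2, 0.0278 for Slfn4, 0.00576 for Ifi209 and 0.0316 for Trem3.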

How the results depend on the processing

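The fits with or within the FRC library sets were tests chosen only after the result was seen, and the others were planned. With RLE scaling the counts of genes stayed within 1.5 times those reported in the 7 comparisons (2384, 1017, 208, 2074, 1843, 18 and 1375, in the order FRC by age, Ly6C-high by age, Ly6C-low by age, gates at day 5, gates at day 14, difference between gates, FRC against monocyte-macrophages). DESeq2 gave 3569 genes for FRC by age, 474 for Ly6C-low by age, 92 for the difference between gates and 2393 for FRC against monocyte-macrophages, and limma-voom gave 6030, 400, 8 and 4226, and the cause was not tested. With no low-count filter the count was 467 for Ly6C-low by age and 134 for the difference between gates, and the cause was not tested. A 2-fold minimum, which can only lower a count, gave 1414, 482, 109, 1117 and 1032 genes in the first 5 comparisons. A fit of all 20 libraries gave 318 genes for Ly6C-high by age, 10 for Ly6C-low by age, 1231 and 1059 between the gates at day 5 and day 14, and 4 for the difference between gates, and a fit of the 2 groups alone gave 1241 between the gates at day 14; the cause was not tested. Within FRC library set 1, with 1 day 14 library assumed to vary like the day 5 libraries, the count was 107, and within set 2, with 1 day 5 library, 2273. Replicate number as a block gave 2646, 924, 196, 1788, 1432, 19 and 1837 genes (9 of the 18 calls for the difference between gates kept), and the pairing it assumes was not borne out, since same-numbered libraries correlated between -0.17 and 0.40 in FRC.

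Leaving out each library in turn, the counts ranged from 1124 to 4615 for FRC by age, from 563 to 915 for Ly6C-high by age, from 36 to 324 for Ly6C-low by age, from 1546 to 1772 and from 886 to 1760 between the gates at day 5 and day 14, from 5 to 49 for the difference between gates, and from 625 to 3112 for FRC against monocyte-macrophages. A library fewer lowers the power of a test, and the rises without FRC day 5 replicate 4 and without FRC day 14 replicate 1 went with the library sets; the cause was not tested further. A lone Ly6C-low day 14 library was assumed to vary like the other groups. Of the values of named genes that were called, 1 changed direction, Nkg7 in FRC against monocyte-macrophages, at 1.12 without FRC day 5 replicate 3 against -5.43 as reported and -6.69 to 1.12 over the libraries left out (the cause was not tested). When libraries were left out, calls of named genes were lost in 92 values for FRC by age (709 kept), 68 for Ly6C-high (394), 89 for Ly6C-low (141), 37 and 64 between gates (472 and 371), 34 for the difference between gates (76) and 236 for FRC against monocyte-macrophages (1283). The gene list calls lost with an estimated correlation numbered 71, and 2 were lost with RLE scaling. With fry 20 were lost, and the lists called went from 13 to 5 for Ly6C-low by age and from 2 to 0 for the difference between gates. Over the libraries left out, 51 list calls were lost and 54 gained. In simulated data, which held no library sets, the FRC test found 16% of genes with a planted log2 change of 1, so changes of that size were often missed there. The cause was not tested.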

Other observations

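The tests on B cell genes in FRC and on interferon genes in Ly6C-high cells were chosen only after the result was seen.

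Ligands in FRC and their receptors in the monocyte-macrophage gates were measured in the same series. Csf1, a growth factor of macrophages, had 129 ± 30 CPM in day 5 FRC and 226 ± 22.4 CPM in day 14 FRC, and Il34, another ligand of its receptor, 20.1 ± 5.11 and 38.3 ± 5.16 CPM. Csf1r, the receptor, had 4208 ± 96.7 and 4225 ± 483 CPM in Ly6C-high cells and 5357 ± 152 and 4979 ± 6.91 CPM in Ly6C-low cells at the 2 ages. Cx3cl1 had 0.964 ± 0.972 CPM in day 5 FRC and 22.7 ± 9.59 CPM in day 14 FRC, with Cx3cr1, its receptor, at 935, 1281, 1129.5 and 1344 CPM in Ly6C-high day 5, Ly6C-high day 14, Ly6C-low day 5 and Ly6C-low day 14 cells. Ccl2 had a mean of 3347 CPM in day 5 FRC, against 15.8 CPM in Ly6C-high and 543 CPM in Ly6C-low cells of that age.

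Tnf, which encodes tumour necrosis factor, had higher group means in the monocyte-macrophage gates than in FRC, whereas the genes of its receptors were detected in both lineages. Tnf had 74 ± 11.9 and 36.1 ± 12.1 CPM in Ly6C-high cells and 181 ± 103 and 95 ± 22.4 CPM in Ly6C-low cells at day 5 and day 14, and at most 2.84 CPM in FRC. Tnfrsf1a, which encodes a receptor for it, had 197 ± 44.9 and 288 ± 25.2 CPM in FRC, 327 and 355 CPM in Ly6C-high and 248 and 242 CPM in Ly6C-low cells. Tnfrsf1b, which encodes another receptor, had 47.6 and 172 CPM in FRC and group means of 937 to 1627 CPM in monocyte-macrophages. Ccl19, a chemokine of the T cell zone, had 31.3 ± 16.6 and 18.9 ± 6.62 CPM in FRC, and Cxcl13, a chemokine of B cell follicles, 886 ± 405 and 859 ± 266 CPM.

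Of the B cell list, 1 gene was lower in day 14 FRC and 4 were higher, as was Cr2. B cell RNA in the sort, whose gate removes CD45+ cells, was argued against by Cd79a, Cd79b, Ms4a1, Cd19 and Igkc, which are abundant in B cells and stayed at most at 3.10 CPM (Igkc) in the day 14 libraries, while the lowest Fcer2a was 11.7 CPM. The division into library sets was argued against as the whole cause, since 4 of these 5 genes still rose with library set as a term (Fcer2a at 4.80, Blnk at 3.52, Ighm at 2.78 and Spib at 0.93), and the fifth, Cr2, had 2.21 with adjusted p = 0.13. The set term was chosen in these same libraries, so p-values with it may be too small. A change of FRC with age, or of the mix of stromal cells inside the gate, stays open and was not tested.

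Of 37 interferon response genes 20 were higher in day 14 Ly6C-high cells, and the list had adjusted p = 0.14 with an estimated correlation. A single library as the whole cause was argued against, since of the 20 genes that rose 14 still rose without day 14 replicate 2, and 19 without either of the others. RNA from NK cells, a source of interferon-gamma that the gate excludes by NK1.1, was argued against as the whole source of these transcripts. The lowest NK list sum at day 14, 41.2 CPM, lay within the day 5 range of 29.7 to 53.4 CPM. The interferon list summed to at least 5194 CPM in every day 14 library and at most 3995 CPM at day 5. In mean the NK list rose by 73.9 CPM, 2.77% of the 2669 CPM of the interferon list, but no NK cell profile was used to scale the 2 lists. A change of the cells with age stays open and was not tested.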
